A study of Mus musculus with 22 samples.

How the data were processed

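The deposited files hold transcript-level output of RSEM, with 1 file per library. Per the file headers they give, for each of 103732 transcripts, an expected count (the estimated number of reads from that transcript), TPM, FPKM, the percent of its gene's output that the transcript makes up, and its length and effective length. Expected counts of the authors were summed over the transcripts of each gene, which gave 43430 genes, of which 42546 matched GENCODE M21 on GRCm38 by identifier. The deposited TPM, FPKM and percent were not used in tests, and effective length, in bases, served only for offsets in an alternative. Per the submitters' processing notes, Trimmomatic 0.33, STAR 2.5.2, RSEM 1.3.3 and DESeq2 (no version given) were used with the mm10 genome. The notes do not state the role and order of the tools or the annotation release. Per the labels, mice were perfused with cold saline and mild paraformaldehyde and quenched with glycine, ZsGreen-positive cells were sorted, RNA was extracted with a kit for fixed tissue, and libraries were made with SMART-seq v4. No column was left without a sample.

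Gene counts from all 22 libraries entered 1 fit of edgeR 4.0.16 in R 4.3.3, with TMM scaling (factors 0.942 to 1.094), robust quasi-likelihood dispersions (common dispersion 0.0444) and a mean per group of state and time. A gene was tested when it passed the edgeR filter on low counts (minimum count 10, minimum total 15), which kept 15084 genes and left out 28346. All comparisons were contrasts of the 6 group means, with p-values adjusted by Benjamini-Hochberg and 0.05 as the threshold. Day 1 and day 3 were averaged over both times before comparison with the average of the uninjured groups. CPM values are scaled by TMM and are relative to the other RNA of a library, so they are not amounts per cell. Errors of log2 fold changes are standard errors (SE) implied by the F test, the absolute log2 change over the square root of F. They are less reliable at low counts. Intervals and floors cover counting error only, and a group without counts was given a floor of 3 counts over the group. DESeq2 1.42.0 and limma 3.58.1 (voom with quality weights) served as other tools. Levels per library were summarised with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and exact permutation tests were two-sided.

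Before the data were examined, 27 gene lists with 474 genes were written, 18 of pathways and 9 of markers of other cell types, and 473 of the genes were found by symbol (Ero1a was not). Lists were tested by camera with a preset correlation of 0.01 between genes and again with an estimated correlation, each adjusted over the lists of a comparison. The genes named were chosen by a rule from the same time. It took the 8 highest and 8 lowest log2 fold changes among genes past the threshold with a mean of at least 10 CPM in the higher group, CPM ranges that did not overlap and a gene symbol, and up to 4 members with the smallest p of each list. It also took all clock genes in comparisons of ZT16 with ZT4, the 5 smallest p-values for tests of a difference in the time effect, and Pax7, Myf5, Myod1, Myog, Ccl2 and Nampt. Not every gene the rule allows is named, and some are not reported here.

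Recovery was measured in counts simulated from the fitted dispersions, the library sizes and mean levels of the real data, with 200 genes changed by known folds. The changed genes were drawn from those with a mean of at least 1 CPM over all libraries, so the rates do not cover genes below that. Each gene had 1 dispersion for all groups. Real uninjured replicates differed more, with correlations of log2 CPM of 0.9316 to 0.966, against 0.96 to 0.9828 in injured groups. The rates may be too favourable for uninjured libraries. For day 1 against uninjured, each gene also had the same mean in all libraries before the change, unlike the real data. In uninjured ZT16 against ZT4, edgeR recovered 17.9% of 67 genes at 1.5-fold, 40.3% of 67 at 2-fold and 78.8% of 66 at 4-fold, among 14786 genes tested, and called 8 unchanged genes. In day 1 against uninjured it recovered 37.3% of 67 genes at 1.5-fold, 76.1% of 67 at 2-fold and 98.5% of 66 at 4-fold, among 14570 genes, and called 4 unchanged genes. In the test of the time effect at day 1 against uninjured it recovered 1.5% of 67 at 1.5-fold, 37.3% of 67 at 2-fold and 60.6% of 66 at 4-fold, among 14778 genes, and called 1 unchanged gene.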

Results

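RNA was measured in 22 libraries of muscle stem cells from mice whose Pax7-expressing cells carry the fluorescent protein ZsGreen. Pax7 is the transcription factor that marks muscle stem cells. The cells came from hindlimb muscle that was uninjured, or 1 or 3 days after injury with cardiotoxin, a snake toxin that destroys myofibers and sets off regeneration. Each state was studied at ZT4 and ZT16, zeitgeber times counted in hours from lights on, so ZT4 lies in the light phase and ZT16 in the dark phase of a standard light cycle. There were 3 libraries per time in uninjured muscle, and 4 per time at day 1 and at day 3. The labels attach ZT4 and ZT16 to the injury and do not give the hour of collection. They also do not say whether replicates are separate mice. Library totals ranged from 5965957 to 9751536 estimated counts, with 15777 to 22992 genes detected per library. Levels below are counts-per-million values (CPM), given as mean ± SD. Changes are log2 fold changes ± SE from 1 edgeR fit of all libraries. Gene positions are on GRCm38, with the annotated start and end of the gene.

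In uninjured muscle, ZT16 was compared with ZT4 to see how the stem cells differ between light and dark phases before any injury. Genes of the clock differed between the times. Arntl, which encodes the clock activator BMAL1 (chromosome 7, 113207465 to 113314126), fell from 35.4 ± 12.8 to 8.55 ± 4.57 CPM (n = 3 and 3, log2 −2.05 ± 0.34). Its partner Npas2 fell as well (−1.85 ± 0.56). So did Nr1d1, which encodes the repressor REV-ERB alpha (−0.95 ± 0.18). Per2, a repressor of BMAL1 (chromosome 1, 91415982 to 91459324), rose from 28.0 ± 25.5 to 202 ± 43.6 CPM (2.88 ± 0.45). The repressors Per3 (1.35 ± 0.27), Cry1 (1.82 ± 0.27), Cry2 (0.91 ± 0.28), Nr1d2 (0.87 ± 0.16), Bhlhe40 (2.18 ± 0.64) and Bhlhe41 (1.47 ± 0.24) also rose. So did the clock-driven genes Tef (1.12 ± 0.15), Hlf (2.75 ± 0.46) and Usp2 (2.95 ± 0.52) and the D-box repressor Nfil3 (2.92 ± 0.61). Of 14 repressor and output genes controlled through E-boxes, 10 rose, 1 fell and 3 did not pass, with 12 up and 1 down when adjusted over the list alone. The list moved up by camera, adjusted p = 5.94e-10 with the preset and adjusted p = 0.0401 with an estimated correlation. The 3 that missed the threshold were Per1 (1.02 ± 0.51), Dbp (0.46 ± 0.21) and Ciart (0.95 ± 0.41). Of 7 activators and RORE-driven genes, 1 rose, 2 fell and 4 did not pass (camera adjusted p = 0.688). Cry2 lost its call without any 1 of the uninjured libraries other than ZT4 replicate 3, Npas2 without ZT4 replicate 3 or ZT16 replicate 2 or 3, and Bhlhe40 without ZT4 replicate 1 or 2 or ZT16 replicate 1 or 3 (adjusted p from 0.057 to 0.134 in edgeR). Per1 gained a call without ZT4 replicate 3 (adjusted p = 0.00941).

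**Figure D1:**
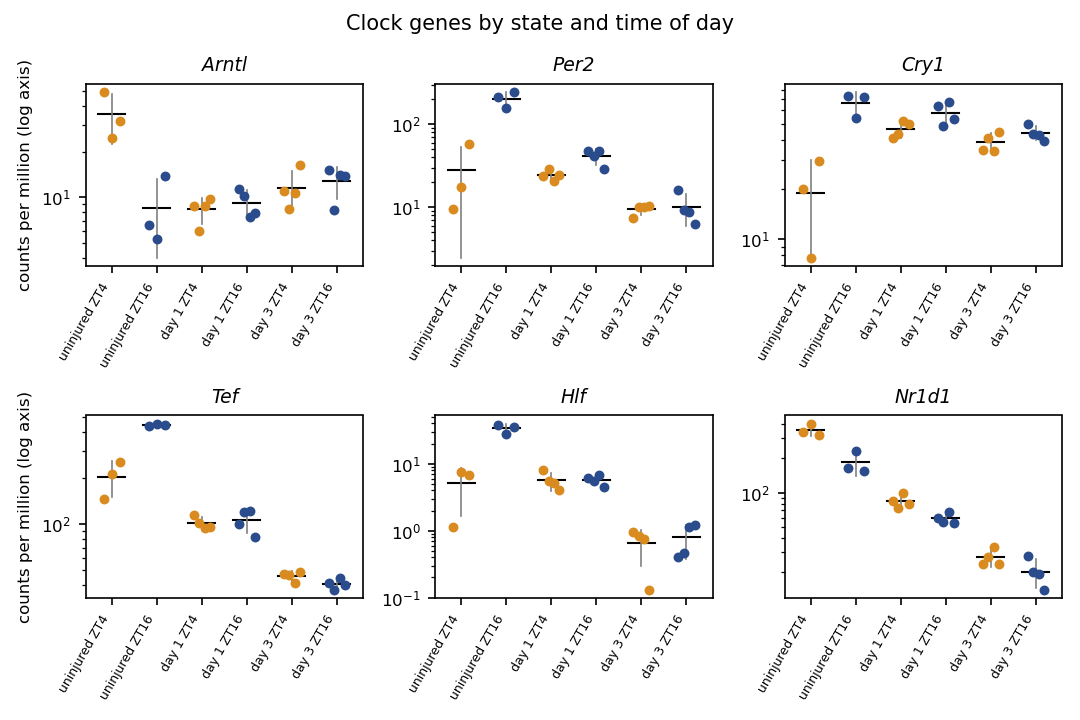
CPM (log axis) of 6 clock genes in each library, by state and zeitgeber time; points are libraries, black lines group means and grey lines ± SD. Arntl in uninjured muscle averaged 35.4 at ZT4 and 8.55 at ZT16, while Per2 averaged 28.0 and 202.

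Other gene groups also differed between the times in uninjured muscle. All 20 immediate early and stress genes rose at ZT16 (camera adjusted p = 4.09e-14, but adjusted p = 0.335 with an estimated correlation). Among them were Socs3, a feedback inhibitor of cytokine signalling (5.19 ± 0.91), Egr2 (6.29 ± 1.11), Junb (4.41 ± 0.81), Klf2 (4.48 ± 0.72) and Klf4 (4.24 ± 0.75), all transcription factors apart from Socs3. Csrnp1, another early response gene, rose by 5.51 ± 1.03. The mean log2 CPM of these 20 genes was 10.58 and 10.55 in ZT16 replicates 1 and 3, against 6.54 in ZT16 replicate 2 and 4.94 to 6.37 in the ZT4 libraries. Of 30 oxidative phosphorylation genes, 21 fell, none rose and 9 did not pass, with 25 down when adjusted over the list alone. Cox6b1 (−0.81 ± 0.13) and Cox8a (−0.75 ± 0.12), subunits of cytochrome c oxidase, were among them (camera adjusted p = 5.94e-10, adjusted p = 0.242 with an estimated correlation). Of 17 hypoxia response genes, 7 rose, 1 fell and 9 did not pass (camera adjusted p = 0.000497, adjusted p = 0.0401 with an estimated correlation). They included Ddit4, an inhibitor of mTORC1 (2.53 ± 0.37), the glucose transporter gene Slc2a3 (1.73 ± 0.27) and the angiogenic factor Vegfa (1.20 ± 0.20). Glycolysis genes went both ways, 3 up and 3 down of 15, with Eno1 at −0.66 ± 0.09 and Gapdh at −0.67 ± 0.12.

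Of 26 chemokine and cytokine genes, 8 rose, 1 fell and 17 did not pass in the same comparison (camera adjusted p = 0.00212, adjusted p = 0.637 with an estimated correlation). Ccl2, a monocyte attractant, rose by 2.46 ± 0.76, Cxcl10 by 4.13 ± 0.87, the macrophage growth factor gene Csf1 by 0.85 ± 0.19 and Cxcl12 by 0.74 ± 0.18. Of 21 NF-kB response genes, 7 rose and 14 did not pass (camera adjusted p = 0.00753, adjusted p = 0.796 with an estimated correlation), with Nfkbiz at 4.78 ± 0.97. Of 20 unfolded protein and heat shock genes, 8 rose, 1 fell and 11 did not pass (camera adjusted p = 0.000799, adjusted p = 0.637 with an estimated correlation), with the endoplasmic reticulum cochaperone gene Dnajb9 at 1.48 ± 0.21. Of 17 genes of NAD metabolism 2 rose, Nampt, the rate-limiting enzyme of NAD salvage (0.79 ± 0.16), and Nnmt, which methylates nicotinamide (3.36 ± 0.59). Pax7 did not pass (−0.07 ± 0.16). The macrophage marker Cd68 rose by 2.71 ± 0.58 at low levels, 0.932 ± 0.174 to 6.28 ± 2.88 CPM, as the only 1 of 18 macrophage genes past the threshold, with 15 of the 18 positive (median 0.87, camera adjusted p = 0.0971). The mean log2 CPM of the macrophage genes was 1.014 in ZT16 replicate 1 and at most −0.087 in the other uninjured libraries, and that of the chemokine genes 2.226 and at most 1.028. The smooth muscle genes Tagln (−1.65 ± 0.18) and Acta2 (−1.11 ± 0.21) fell. Of 8 mural genes 2 fell, none rose and 4 were positive (median 0.2, camera adjusted p = 0.293). The 20 lists not past the camera test had adjusted p from 0.0971 to 0.942.

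Among the widest falls at ZT16 were those of Agtr2, an angiotensin II receptor gene (−5.05 ± 1.10), and Angptl4, an inhibitor of lipoprotein lipase (−3.85 ± 0.63). Fam198b (−3.04 ± 0.47), Akr1c14 (−2.79 ± 0.77), Olfm2 (−2.70 ± 0.59), the cholesterol synthesis enzyme gene Msmo1 (−2.66 ± 0.31) and the cadherin gene Cdh4 (−2.65 ± 0.58) also fell. Has1, a hyaluronan synthase gene, had no counts at ZT4 and 12.2 ± 10.7 CPM at ZT16, at least 94.1-fold higher against a floor of 3 counts over the group. Fgfr2, a fibroblast growth factor receptor gene, had 0.0376 ± 0.0652 CPM at ZT4 from 1 count and 11.6 ± 6.79 at ZT16. By edgeR, 2663 of 15084 genes passed, 1287 up and 1376 down, of which 543 rose and 359 fell at least 2-fold. Without ZT16 replicates 1 and 3, which leaves ZT16 replicate 2 alone in its group, 467 genes passed, and 408 of them were among the 2663, all with the same sign. Arntl, Per2, Per3, Cry1, Tef, Hlf, Bhlhe41, Msmo1, Fam198b, Fgfr2, Ddit4, Dnajb9, Csf1, Cxcl12, Nampt, Eno1, Gapdh, Tagln and Acta2 kept their calls. The other genes named as risen or fallen lost them, though Angptl4, Akr1c14, Olfm2, Cdh4, Npas2 and Cry2 stayed within 1 SE of the values above. The chemokine, NF-kB and unfolded protein lists also lost their calls, and the NF-kB list changed direction. The count was 1768 without ZT16 replicate 1 and 577 with these 6 libraries alone. The main fit shared 1 spread per gene over all groups, and uninjured replicates differed more than injured ones. Its errors may be too small here. Has1 lost its call without any 1 library other than ZT16 replicate 2, Ccl2 without any ZT4 library or ZT16 replicate 1, and the NF-kB list without ZT4 replicate 1 or ZT16 replicate 1 (adjusted p from 0.0527 to 0.257).

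**Figure D2:**
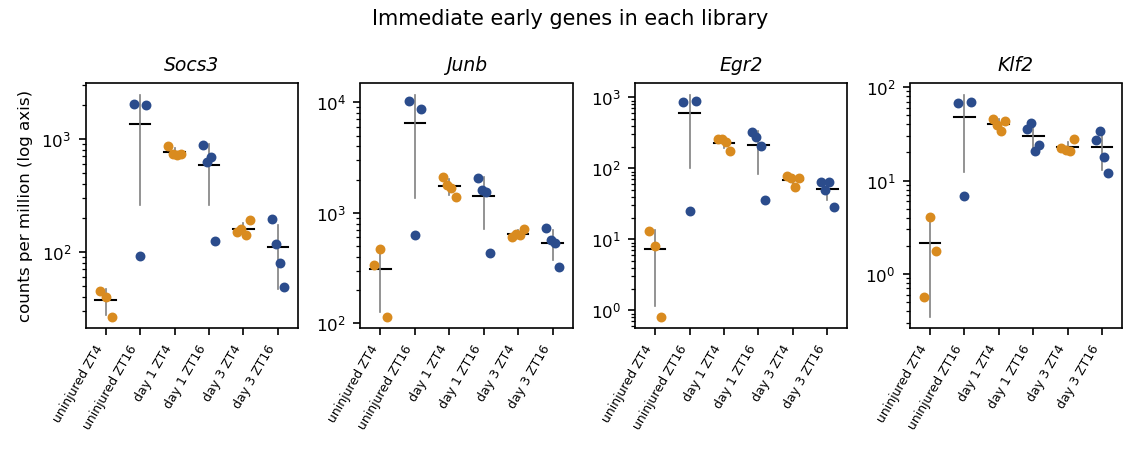
CPM (log axis) of Socs3, Junb, Egr2 and Klf2 in each library, by state and zeitgeber time; points are libraries, black lines group means and grey lines ± SD. In uninjured muscle at ZT16, replicates 1 and 3 lie far above replicate 2, and Socs3 averaged 1360 ± 1100 against 37.1 ± 9.79 at ZT4.

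At day 1 after injury, ZT16 was compared with ZT4 to see whether the hour of injury shaped the early response. No gene passed in edgeR (920 of 15084 at an unadjusted p under 0.05, smallest adjusted p = 0.187), against 27 in DESeq2 and 46 in limma voom. No clock gene passed, but some differed by more than 1 SE. Per2 was at 24.3 ± 3.24 and 41.3 ± 8.74 CPM at ZT4 and ZT16 (n = 4 and 4, 0.76 ± 0.38), Cry1 at 0.33 ± 0.22, Nr1d1 at −0.49 ± 0.16 and Dbp at −0.55 ± 0.19. Per2, Cry1 and Nr1d1 had the sign they had in uninjured muscle, and Dbp the other. The 14 E-box genes had camera adjusted p = 0.481. Markers of leukocytes, present although ZsGreen-positive cells were sorted, had lower means at ZT16. All 6 measured neutrophil genes were lower, and all 6 fell when adjusted over the list alone (camera adjusted p = 1.39e-10, adjusted p = 0.0781 with an estimated correlation). S100a9, a neutrophil granule protein gene, was at 39.8 ± 22.5 CPM at ZT4 and 11.4 ± 4.61 at ZT16 (−1.80 ± 0.44), with Cxcr2 at −2.11 ± 0.58 and Mmp9 at −1.38 ± 0.37. All 18 macrophage and monocyte genes were lower (camera adjusted p = 2.24e-06, adjusted p = 0.692 with an estimated correlation), with Tyrobp at −0.78 ± 0.29 and Cd68 at −0.57 ± 0.27. Myofiber genes were lower in 17 of 18 (camera adjusted p = 1.33e-10, adjusted p = 0.189 with an estimated correlation; 4 fell and 1 rose over the list alone), with the fast troponin gene Tnnc2 at −1.14 ± 0.31. Chemokines and cytokines were lower in 20 of 26 (camera adjusted p = 0.000849, adjusted p = 0.692 with an estimated correlation), with the inflammatory cytokine gene Il1b at −1.86 ± 0.70, Tnf at −1.18 ± 0.56 and Ccl2 at −0.69 ± 0.42.

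In the same day 1 comparison, all 23 mitosis genes had positive values (camera adjusted p = 4.26e-07, adjusted p = 0.692 with an estimated correlation), with the spindle checkpoint kinase gene Bub1b at 0.67 ± 0.23 and Plk1 at 0.70 ± 0.28. Myog, a regulator of differentiation, was at 1.19 ± 0.55. The ribosome biogenesis (0.0197), MHC class I (0.0212), erythroid (0.0212), NF-kB (0.0151) and immediate early (0.0338) lists were lower by camera adjusted p, with adjusted p from 0.692 to 0.789 with an estimated correlation. Each of these 5 was lost without at least 1 library, as far as adjusted p = 0.92 for the immediate early list and 0.337 for the NF-kB list without ZT16 replicate 4. The median CPM of the neutrophil genes was 5.048 ± 1.99 at ZT4 and 1.345 ± 0.7554 at ZT16 (exact permutation p = 0.02857, two-sided, the smallest that 4 against 4 can give; adjusted p = 0.3714 over 39 such tests). The mural genes had the same exact permutation p and adjusted p in the other direction, 6.527 ± 0.4083 at ZT4 and 7.778 ± 0.4858 at ZT16. The macrophage genes were at 95.43 ± 14.95 and 65.39 ± 19.96 (exact permutation p = 0.05714, adjusted p = 0.5571). Their mean log2 CPM in ZT16 replicate 1, 6.467, lay within the range of the ZT4 libraries, 6.181 to 6.828. The other ZT16 libraries were at 5.289 to 5.881. With no filter on low counts 270 genes passed, and without ZT16 replicate 4 there were 10. Simulated changes were recovered in this comparison at 34.3% of 67 for 1.5-fold, 58.2% of 67 for 2-fold and 83.3% of 66 for 4-fold (14784 genes tested).

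At day 3, the same question was asked of the later response, and again no gene passed in edgeR (1003 of 15084 at an unadjusted p under 0.05, smallest adjusted p = 0.143), against 4 in DESeq2 and 0 in limma voom. Extracellular matrix genes had lower values at ZT16 in 24 of 27 (camera adjusted p = 1.65e-06, adjusted p = 0.65 with an estimated correlation), with the matrix protease gene Mmp14 at −0.52 ± 0.13, the basement membrane gene Nid1 at −0.55 ± 0.20 and Col4a2 at −0.46 ± 0.17. Markers of fibro-adipogenic cells, which make matrix, were lower in 12 of 14 (median −0.32 against −0.39 for matrix, camera adjusted p = 0.0736), and their summed level was 3630 ± 899.6 CPM at ZT4 and 2578 ± 290.3 at ZT16. Oxidative phosphorylation genes were higher in 27 of 30 (camera adjusted p = 0.000125, adjusted p = 0.65 with an estimated correlation), with Uqcrq at 0.23 ± 0.09 and Cox8a at 0.26 ± 0.11. Of the 14 E-box genes none passed and 1 fell over the list alone, with Nr1d2 at −0.62 ± 0.14 and Nr1d1 at −0.40 ± 0.17 (camera adjusted p = 0.0172, adjusted p = 0.65 with an estimated correlation). The chemokine list was lower (camera adjusted p = 0.0202) and the interferon list higher (0.0172), each with adjusted p = 0.65 with an estimated correlation. Leukocyte markers were lower beside the chemokines, neutrophil genes in 5 of 6 (median −0.67, camera adjusted p = 0.05, at the threshold) and macrophage genes in 14 of 18 (0.0941). The summed level of the neutrophil genes was 15.7 to 19.52 CPM at ZT4 and 7.32 to 11.79 at ZT16. Most of that sum was Mmp9, at 12.1 ± 0.818 and 6.52 ± 0.893. The median CPM of the neutrophil genes was 0.2986 ± 0.2359 at ZT4 and 0.03845 ± 0.0769 at ZT16 (exact permutation p = 0.08571, adjusted p = 0.5571 over 39 tests). The neutrophil attractant gene Cxcl5 was at −1.67 ± 0.38, Ccl2 at −0.43 ± 0.47 and Myod1 at 0.26 ± 0.11. The E-box list lost its call without ZT4 replicate 2 or ZT16 replicate 4, the chemokine list without ZT4 replicate 3 or 4 or ZT16 replicate 3 or 4, and the interferon list without ZT4 replicate 1 or 2 or ZT16 replicate 1 or 3 (adjusted p from 0.0537 to 0.475). Without ZT4 replicates 1 and 2 and ZT16 replicates 3 and 4 together, all 3 lists lost their calls (0.577 for E-box, 0.958 for the others) and the interferon list changed direction. With no filter on low counts 127 genes passed. Simulated changes were recovered at 25.4% of 67 for 1.5-fold, 61.2% of 67 for 2-fold and 83.3% of 66 for 4-fold (14779 genes tested).

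Day 1 was compared with uninjured muscle, averaged over both times, to describe how the sorted cells changed after injury. Pax7 (chromosome 4, 139737062 to 139833528) fell from 322 ± 28.3 to 58.2 ± 11.3 CPM (n = 6 and 8, −2.47 ± 0.11), and Myf5 fell by 1.60 ± 0.17. The myogenic determination gene Myod1 (chromosome 7, 46376474 to 46379099) rose from 253 ± 48.5 to 1340 ± 79.9 CPM (2.41 ± 0.09). Of 21 quiescence and Notch genes, 19 fell and 2 rose (camera adjusted p = 5.68e-10, adjusted p = 0.0509 with an estimated correlation). Foxo1, a transcription factor of quiescent cells (−2.32 ± 0.12), the cell cycle inhibitor gene Cdkn1c (−5.37 ± 0.38) and the Notch targets Hey1 (−2.15 ± 0.12) and Hes1 (−2.66 ± 0.15) were among those that fell. All 22 DNA replication genes rose (camera adjusted p = 1.89e-27, adjusted p = 0.0448 with an estimated correlation), with the replicative helicase genes Mcm3 at 3.74 ± 0.12 and Mcm7 at 2.32 ± 0.08. All 21 ribosome biogenesis genes rose (camera adjusted p = 1.02e-16, adjusted p = 0.0448 with an estimated correlation), with nucleolin, Ncl, at 2.37 ± 0.07 and Nop58 at 2.02 ± 0.08. All 23 mitosis genes rose (camera adjusted p = 1.16e-06, adjusted p = 0.47 with an estimated correlation), with Cdk1 at 3.76 ± 0.24 and Cenpe at 2.91 ± 0.18.

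In the same day 1 comparison with uninjured muscle, 12 of 15 glycolysis genes rose, 1 fell and 2 did not pass (camera adjusted p = 3.3e-08, adjusted p = 0.0532 with an estimated correlation), with Eno1 at 2.15 ± 0.07 and Pgam1 at 2.36 ± 0.09. Oxidative phosphorylation had 25 up, 2 down and 3 not passed (camera adjusted p = 0.00142, adjusted p = 0.495 with an estimated correlation), with Cox5a at 1.48 ± 0.08. Unfolded protein genes had 15 up, 4 down and 1 not passed (0.000198, and adjusted p = 0.418 with an estimated correlation). Nampt rose by 1.09 ± 0.10, in a list of NAD metabolism with 4 up and 8 down of 17 that was not past the test (camera adjusted p = 0.874). Of 17 commitment genes, 11 fell, 4 rose and 2 did not pass, and the list was not past the test (camera adjusted p = 0.214). Those that fell included Myog (−4.94 ± 0.39), the fusion protein gene Mymk (−6.04 ± 0.42) and the cardiac actin gene Actc1 (−4.96 ± 0.40). The sarcoplasmic reticulum micropeptide gene Mrln (−6.04 ± 0.26), the organic cation transporter gene Slc22a3 (−6.63 ± 0.54) and the noncoding RNA gene Nctc1 (−5.03 ± 0.33) were among the other widest falls. The tachykinin gene Tac4 went from 25.0 ± 8.22 to 0.0995 ± 0.185 CPM, with no counts at ZT4 of day 1. Of the 14 E-box clock genes, 11 fell, 2 rose and 1 did not pass (camera adjusted p = 0.00534, adjusted p = 0.418 with an estimated correlation), with Dbp at −2.08 ± 0.15, Nr1d1 at −1.85 ± 0.12 and Tef at −1.53 ± 0.10. Of the 7 activators and RORE-driven genes 5 fell and 1 rose, with Rora at −2.23 ± 0.17 and Arntl at −0.99 ± 0.22, and the list was not past the test (camera adjusted p = 0.241). These values average uninjured times that differed. Arntl was at 8.31 and 9.20 CPM at day 1, below uninjured ZT4 (35.4) but near uninjured ZT16 (8.55). Hlf (5.67 and 5.73) and Per2 (24.3 and 41.3) lay near uninjured ZT4 (5.09 and 28.0) and below uninjured ZT16 (33.9 and 202). Dbp, Nr1d1, Tef and Rora were below both uninjured means at each time. The Arntl call was lost without the 2 uninjured ZT16 libraries with high immediate early genes (−0.52, adjusted p = 0.0854).

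Chemokine genes and leukocyte markers were among those that rose at day 1. Of 26 chemokine and cytokine genes, 21 rose, 1 fell and 4 did not pass (camera adjusted p = 0.000125, adjusted p = 0.363 with an estimated correlation). Ccl2 (chromosome 11, 82035571 to 82037453) rose from 6.65 ± 7.91 to 314 ± 106 CPM, Csf1 by 4.16 ± 0.13 and Cxcl5 from 0.305 ± 0.494 to 18.7 ± 6.66 CPM. Other inflammatory lists were not past the test, with 10 up and 4 down of 21 NF-kB genes (camera adjusted p = 0.44), 5 up and 14 down of 26 interferon response genes (0.214) and 7 down of 14 MHC class I genes (0.539). All 18 macrophage and monocyte genes rose (camera adjusted p = 5.68e-10, adjusted p = 0.344 with an estimated correlation), with Cd68 at 5.70 ± 0.31 and Tyrobp at 7.44 ± 0.39. So did all 6 neutrophil genes (0.00144, and adjusted p = 0.371 with an estimated correlation). The summed level of the 18 macrophage genes was 3358 ± 903.5 CPM at ZT4 and 2083 ± 667.1 at ZT16, against 36.1 ± 13.85 and 63.46 ± 38.99 in uninjured muscle. Whether the chemokine and cytokine RNA of the injured libraries came from stem cells or from other cells in the sort was not tested. Several of the widest rises were in leukocyte genes without counts in the uninjured libraries. Against a floor of 3 counts over that group, the macrophage gene Ms4a7 was at least 352-fold higher, the receptor gene Cd300lb at least 298-fold, the protease inhibitor genes Slpi and Serpinb2 at least 294-fold and 290-fold, and the toll-like receptor gene Tlr13 at least 290-fold. From 2 or 3 uninjured counts each, Chil3 went from 0.0476 to 127 CPM, the interleukin-1 antagonist gene Il1rn from 0.0473 to 102 and the cytokine gene Osm from 0.0714 to 83.4. Extracellular matrix had 17 down and 6 up of 27 (camera adjusted p = 0.0156, adjusted p = 0.582 with an estimated correlation), with Col6a1 at −3.08 ± 0.17, Sparc at −1.25 ± 0.07 and the protease inhibitor gene Timp1 at 6.12 ± 0.29. Myofiber genes fell in 15 of 18 (camera adjusted p = 0.0296, adjusted p = 0.582 with an estimated correlation), with Actn3 at −2.55 ± 0.14 and Mylpf at −1.54 ± 0.21. By edgeR, 11347 of 15084 genes passed, 5226 up and 6121 down, of which 2930 rose and 3670 fell at least 2-fold, around a median of −0.125 over all genes. The balance depended on scaling, with 46.1% of calls higher with TMM, 48.6% with RLE size factors and 50.2% with effective-length offsets. The extracellular matrix call was lost without uninjured ZT16 replicate 1 (adjusted p = 0.111).

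**Figure D3:**
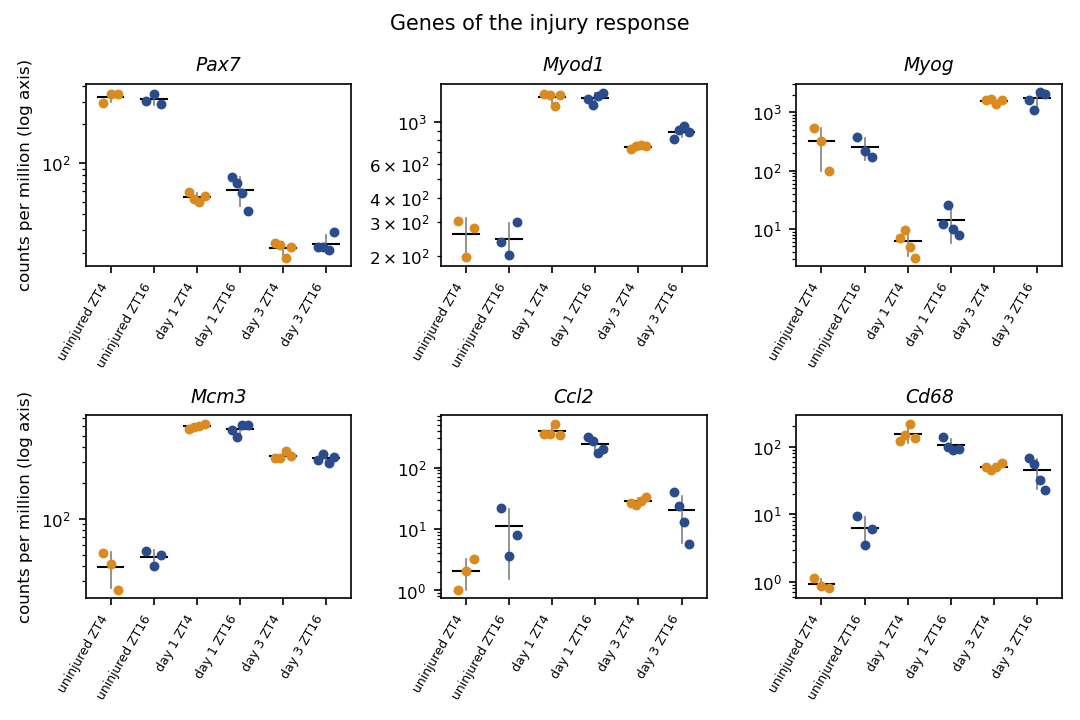
CPM (log axis) of Pax7, Myod1, Myog, Mcm3, Ccl2 and Cd68 in each library, by state and zeitgeber time; points are libraries, black lines group means and grey lines ± SD. Pax7 averaged 322 in uninjured muscle, 58.2 at day 1 and 22.6 at day 3, and Myog averaged 286, 10.1 and 1670.

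Day 3 against uninjured muscle describes cells further along regeneration. Pax7 fell to 22.6 ± 3.12 CPM (−3.83 ± 0.11, n = 6 and 8), Myf5 by 3.33 ± 0.18, Foxo1 by 4.11 ± 0.13 and the surface protein gene Cd34 by 4.06 ± 0.11, with 19 of 21 quiescence and Notch genes down, 1 up and 1 not passed (camera adjusted p = 4.43e-14, adjusted p = 0.0677 with an estimated correlation). Of 17 commitment genes, 13 rose, 3 fell and 1 did not pass (camera adjusted p = 0.0405, adjusted p = 0.491 with an estimated correlation). Myog (chromosome 1, 134289989 to 134292548) rose from 286 ± 157 to 1670 ± 348 CPM (2.55 ± 0.36), Myod1 by 1.69 ± 0.09, the fusion gene Mymx by 5.44 ± 0.31 and Mef2a by 2.67 ± 0.13. All 23 mitosis genes (camera adjusted p = 3.12e-11, adjusted p = 0.275 with an estimated correlation), all 22 DNA replication genes (2.43e-17, and adjusted p = 0.0855 with an estimated correlation) and all 30 oxidative phosphorylation genes (1.67e-13, and adjusted p = 0.0855 with an estimated correlation) rose. Cenpe was at 4.44 ± 0.18, Mcm3 at 2.93 ± 0.11, Cyc1 at 1.86 ± 0.07 and Cox5a at 2.07 ± 0.08. Glycolysis had 13 up and 1 down of 15 (1.09e-09, and adjusted p = 0.0677 with an estimated correlation), with Eno1 at 3.06 ± 0.07. Ribosome biogenesis had 20 up and 1 down (8.57e-07, and adjusted p = 0.227 with an estimated correlation), and the unfolded protein list 14 up and 5 down of 20 (0.00489, and adjusted p = 0.523 with an estimated correlation). Of the 14 E-box clock genes, 12 fell and 2 did not pass (2.01e-07, and adjusted p = 0.0925 with an estimated correlation), with Dbp at −5.44 ± 0.18, Nr1d1 at −3.44 ± 0.13 and Tef at −2.79 ± 0.10.

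In the same day 3 comparison, Ccl2 was up by 2.35 ± 0.45, Csf1 by 2.54 ± 0.13 and the alarmin gene Il33 by 5.64 ± 0.43, with 17 chemokine and cytokine genes up and 6 down of 26 (camera adjusted p = 0.192). Nampt was up by 0.97 ± 0.10, with 5 genes of NAD metabolism up and 6 down of 17 (0.78). All 18 macrophage genes rose (camera adjusted p = 3.2e-05, adjusted p = 0.491 with an estimated correlation), with Cd68 at 4.27 ± 0.31 and Tyrobp at 5.39 ± 0.41. Of 6 neutrophil genes 4 rose (0.237). The basement membrane genes Col4a1 (−3.90 ± 0.14) and Col4a2 (−3.35 ± 0.13) fell among 16 matrix genes down and 11 up (0.0985). Mural genes had 6 down and 1 up of 8 (0.0485, and adjusted p = 0.468 with an estimated correlation). The muscle genes Eno3 (4.71 ± 0.15) and Ttn (4.72 ± 0.18) rose, with 9 of 18 myofiber genes up and 5 down (0.192). The widest falls included Chrdl2 (−8.79 ± 0.27), Nap1l5 (−8.45 ± 0.53), the natriuretic peptide gene Nppc (−8.19 ± 0.67), Chodl (−8.00 ± 0.34) and the thyrotropin receptor gene Tshr, from 48.6 ± 13.8 to 0.24 ± 0.475 CPM. With 1 to 3 counts over the day 3 libraries, Tac4 went from 25.0 ± 8.22 to 0.0174 CPM, Spock3 from 18.9 ± 11.2 to 0.0174 and Slc22a3 from 20.2 ± 12.3 to 0.0592. Against a floor of 3 counts over the uninjured libraries, which had none, R3hdml was at least 361-fold higher, Cthrc1 at least 288-fold, Gpr176 at least 261-fold, Ms4a7 at least 215-fold, Dynap at least 199-fold and Mab21l3 at least 189-fold. From 2 or 3 uninjured counts, Igfbp2, an insulin-like growth factor binding protein gene, went from 0.0444 to 72.4 CPM and Nptx1 from 0.0711 to 60.1. By edgeR, 11606 of 15084 genes passed, 5715 up and 5891 down, of which 3325 rose and 3695 fell at least 2-fold. The commitment list lost its call without uninjured ZT4 replicate 2 or ZT16 replicate 3, and the mural list without uninjured ZT16 replicate 1, day 3 ZT4 replicate 2 or 4 or day 3 ZT16 replicate 2 (adjusted p from 0.0512 to 0.067).

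Day 3 was compared with day 1 to describe the later change in the sorted cells, in libraries where markers of other cells changed as well. Myog rose from 10.1 ± 7.07 to 1670 ± 348 CPM (7.48 ± 0.41, n = 8 and 8), the embryonic myosin gene Myh3 by 10.69 ± 0.55, the fusion genes Mymx by 9.52 ± 0.41 and Mymk by 8.92 ± 0.40, Actc1 by 7.39 ± 0.39, the fetal acetylcholine receptor gene Chrng by 7.10 ± 0.26 and Smim5 by 7.56 ± 0.44. Commitment genes had 12 up, 3 down and 2 not passed of 17 (camera adjusted p = 1.67e-08, adjusted p = 0.124 with an estimated correlation), with Mef2a at 2.13 ± 0.11 and Tnnt2 at 6.39 ± 0.31. Myod1 fell by 0.72 ± 0.08, Myf5 by 1.74 ± 0.16 and Pax7 by 1.36 ± 0.10. Quiescence and Notch genes had 14 down, 4 up and 3 not passed (2.42e-05, and adjusted p = 0.26 with an estimated correlation), with Cd34 at −3.57 ± 0.11 and Chrdl2 at −4.84 ± 0.26. Mitosis genes had 19 up and 4 not passed (1.03e-07, and adjusted p = 0.338 with an estimated correlation), with Ube2c at 1.92 ± 0.11 and Cenpa at 3.07 ± 0.24. DNA replication had 16 down and 4 up of 22 (0.0124, and adjusted p = 0.564 with an estimated correlation), with Mcm7 at −0.68 ± 0.07 and Pcna at −0.90 ± 0.10. Ribosome biogenesis had 19 down of 21 (2.23e-06, and adjusted p = 0.194 with an estimated correlation), with Nop58 at −0.81 ± 0.07. Oxidative phosphorylation had 29 up of 30 (2.17e-16, and adjusted p = 0.124 with an estimated correlation), with Uqcrc1 at 0.93 ± 0.06. Glycolysis had 8 up and 3 down of 15 (0.0323, and adjusted p = 0.4 with an estimated correlation).

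In the same comparison, chemokines and cytokines had 18 down and 2 up of 26 (camera adjusted p = 9.46e-06, adjusted p = 0.194 with an estimated correlation), with Ccl2 at −3.65 ± 0.34, Cx3cl1 at −3.41 ± 0.15, Cxcl12 at −1.82 ± 0.11 and Csf1 at −1.61 ± 0.10, but Il33 at 3.61 ± 0.32. The interferon list was not past the test, with 8 up and 4 down of 26 (0.611). Macrophage genes fell in 15 of 18 (4.06e-05, and adjusted p = 0.338 with an estimated correlation), with Itgam at −3.64 ± 0.31 and Fcgr1 at −2.97 ± 0.28. All 6 neutrophil genes fell (0.00017, and adjusted p = 0.247 with an estimated correlation), with S100a9 at −7.53 ± 0.53 and S100a8 at −6.52 ± 0.52. The chemokine genes Ppbp (−7.43 ± 0.35) and Cxcl3 (−6.95 ± 0.36), Serpinb2 (−7.27 ± 0.42), the arginase gene Arg1 (−7.12 ± 0.35), and the retinoic acid hydroxylase gene Cyp26a1 (−6.42 ± 0.63) were among those that fell most. NF-kB genes had 13 down and 2 up of 21 (0.0124, and adjusted p = 0.48 with an estimated correlation) and immediate early genes 17 down of 20 (0.00431, and adjusted p = 0.564 with an estimated correlation), with Btg2 at −2.75 ± 0.48 and Jund at −1.56 ± 0.29. E-box clock genes had 12 down and 2 not passed of 14 (2.63e-07, and adjusted p = 0.138 with an estimated correlation), with Dbp at −3.36 ± 0.17 and Tef at −1.26 ± 0.10. Fibro-adipogenic genes had 10 up and 2 down of 14 (0.00504, and adjusted p = 0.247 with an estimated correlation), with Col1a2 at 5.45 ± 0.41 and Mfap5 at 3.61 ± 0.34. The laminin genes Lama5 (2.40 ± 0.12) and Lamb1 (2.90 ± 0.19) rose among 12 matrix genes up and 9 down of 27 (0.673). Myofiber genes had 12 up and 4 down of 18 (1.65e-09, and adjusted p = 0.15 with an estimated correlation) and endothelial genes 9 down of 12 (0.0124, and adjusted p = 0.4 with an estimated correlation). By edgeR, 8350 of 15084 genes passed, 4022 up and 4328 down, of which 1525 rose and 1767 fell at least 2-fold. The glycolysis call was lost without day 3 ZT4 replicate 3 (adjusted p = 0.0545), and the DNA replication (0.0547) and NF-kB (0.0558) calls without 4 day 3 libraries that hold many olfactory receptor genes, ZT4 replicates 1 and 2 and ZT16 replicates 3 and 4.

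**Figure D4:**
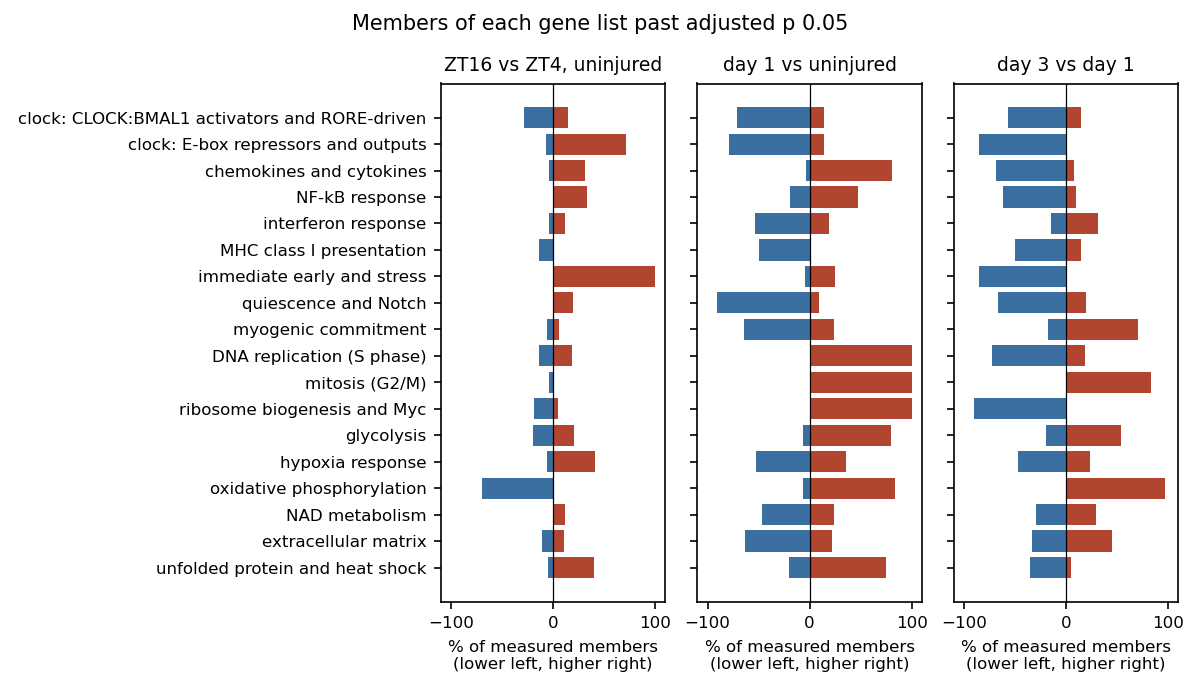
Percent of the measured members of 18 gene lists past adjusted p 0.05 in 3 comparisons; bars to the left are members that fell and bars to the right members that rose. All 20 immediate early genes rose at ZT16 in uninjured muscle, and all 22 DNA replication genes rose at day 1.

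Tests of the difference itself asked whether the effect of ZT16 over ZT4 was the same in uninjured and injured muscle. Uninjured muscle has no hour of injury, while the labels attach the time to the injury in the other groups. The hour of collection is not given. These tests therefore cannot tell an effect changed by injury from 2 unlike meanings of time. Between uninjured muscle and day 1 the effect differed for 1125 of 15084 genes in edgeR, 593 more positive and 532 more negative at day 1. Arntl, which fell at ZT16 in uninjured muscle, differed by 2.19 ± 0.45, and Cry1 by −1.49 ± 0.35, Nr1d2 by −0.89 ± 0.21, Tef by −1.05 ± 0.20, Hlf by −2.73 ± 0.60 and Bhlhe41 by −1.38 ± 0.32. Of the 14 E-box genes, 9 were more negative at day 1 and 5 did not pass, with 11 over the list alone (camera adjusted p = 9.78e-11, adjusted p = 0.0303 with an estimated correlation). Among the smallest p-values were those of Dbi, the acyl-CoA binding protein gene (1.47 ± 0.15), Trip10 (−1.44 ± 0.16), Iqsec3 (1.88 ± 0.22) and the farnesyl diphosphate synthase gene Fdps (2.62 ± 0.29). Immediate early genes were more negative in 17 of 20 (1.27e-20, and adjusted p = 0.175 with an estimated correlation), hypoxia genes in 4 of 17 (0.000203, and adjusted p = 0.0303 with an estimated correlation) and chemokines in 6 of 26 (6.28e-06, and adjusted p = 0.277 with an estimated correlation). Of the markers of other cells, macrophage genes had a median of −1.57 with 16 of 18 negative (0.000441, and adjusted p = 0.582 with an estimated correlation) and myofiber genes a median of −1.28 (7.68e-06, and adjusted p = 0.277 with an estimated correlation). The other 7 marker lists were not past the test and went both ways, with neutrophil genes positive in 4 of 6 (median 1.24, 0.646) and 2 of 8 mural genes more positive (median 0.18, 0.133). Oxidative phosphorylation genes were more positive in 8 of 30 (1.36e-07, and adjusted p = 0.277 with an estimated correlation). The NF-kB (7.79e-05), unfolded protein (0.00844) and interferon (0.00849) lists were more negative and the mitosis list more positive (0.00501), with adjusted p from 0.352 to 0.838 with an estimated correlation. Without uninjured ZT16 replicates 1 and 3, which leaves 1 ZT16 library, the NF-kB and unfolded protein calls were lost, and the unfolded protein list turned positive. The unfolded protein call was also lost without uninjured ZT4 replicate 3 (0.146) or ZT16 replicate 3 (0.0987), the interferon (0.0549) and mitosis (0.134) calls without ZT16 replicate 2, and the mitosis call also without ZT4 replicate 1 (0.84). The count of genes was 134 without uninjured ZT16 replicates 1 and 3, 648 and 728 without each of them alone, 514 with the 4 groups alone and 737 in limma voom. Without both libraries Arntl, Dbi, Trip10, Iqsec3 and Fdps kept their calls and the 5 other clock genes named lost them (adjusted p from 0.052 to 0.245). With 1 uninjured ZT16 library left, those 5 stood at −1.17 for Cry1, −0.74 for Nr1d2, −1.05 for Tef, −2.41 for Hlf and −1.59 for Bhlhe41, each within 1 SE of the value above.

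Between uninjured muscle and day 3 the effect of time differed for 1927 genes, 1026 more positive and 901 more negative at day 3. Dbi (1.74 ± 0.15), Trip10 (−1.78 ± 0.16), Iqsec3 (2.00 ± 0.22), the Kruppel-like factor gene Klf13 (−2.31 ± 0.25) and the cell cycle kinase gene Wee1, itself a clock target (−3.25 ± 0.36), had the smallest p-values. Arntl differed by 2.19 ± 0.44, Nr1d2 by −1.49 ± 0.21, Tef by −1.30 ± 0.20, Bhlhe41 by −1.55 ± 0.32 and Cry1 by −1.64 ± 0.35. Of the 14 E-box genes, 11 were more negative and 3 did not pass, with 12 more negative and 1 more positive over the list alone (camera adjusted p = 4.8e-10, adjusted p = 0.0444 with an estimated correlation). Hypoxia genes were more negative in 5 of 17 (0.000161, and adjusted p = 0.0444 with an estimated correlation), immediate early genes in 18 of 20 (1.32e-14, and adjusted p = 0.3 with an estimated correlation) and oxidative phosphorylation genes more positive in 17 of 30 (1.39e-11, and adjusted p = 0.163 with an estimated correlation). Chemokines were more negative in 8 of 26 (0.000101, and adjusted p = 0.406 with an estimated correlation). The macrophage list, with a median of −1.01 and 15 of 18 negative (0.0292), and the NF-kB (0.0292), unfolded protein (0.0358) and extracellular matrix (0.0446) lists were also more negative, each with adjusted p = 0.833 with an estimated correlation. These 4 lost their calls without uninjured ZT16 replicate 1 (adjusted p from 0.0719 to 0.265), among other libraries. Without uninjured ZT16 replicates 1 and 3 together, the NF-kB, extracellular matrix and unfolded protein lists changed direction. The other 8 marker lists were not past the test, with all 6 neutrophil genes positive (0.648). The count was 473 without uninjured ZT16 replicates 1 and 3 and 661 without the 4 day 3 libraries that hold many olfactory receptor genes. Without those 4, Arntl (adjusted p = 0.0611) and Cry1 (0.0657) lost their calls, and Cry1 also lost its call without the 2 uninjured libraries (0.122), at 1.86, −1.57 and −1.31, each within 1 SE of the value above.

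Between day 1 and day 3 the effect of time differed for no gene in edgeR (711 at an unadjusted p under 0.05, smallest adjusted p = 0.152), for 4 in DESeq2 and for 0 in limma voom. Mitosis genes were more negative at day 3 in 22 of 23 (camera adjusted p = 0.000399), oxidative phosphorylation genes more positive in 26 of 30 (0.000193) and myofiber genes more positive in 13 of 18 (0.000193). The interferon (0.000972), MHC class I (0.0054) and ribosome biogenesis (0.0102) lists were more positive and the extracellular matrix list more negative (0.00172). All 7 lists had adjusted p = 0.724 with an estimated correlation. With no filter on low counts 77 genes passed, and without day 1 ZT4 replicate 2 there was 1. The myofiber (adjusted p = 0.613), interferon (0.4) and MHC class I (0.266) calls were lost without the 4 day 3 libraries named above, the extracellular matrix call without day 3 ZT4 replicate 4 (0.0732), the interferon call also without day 1 ZT16 replicate 4 (0.0506), and the ribosome biogenesis call without day 1 ZT16 replicate 2, day 3 ZT4 replicate 1 or day 3 ZT16 replicate 2 (0.0756 to 0.219).

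**Figure D5:**
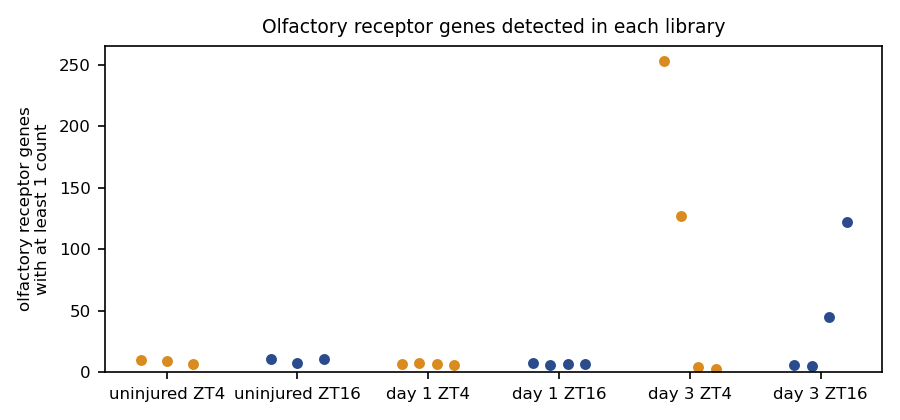
Number of olfactory receptor genes with at least 1 count in each library, by state and zeitgeber time; each point is a library. Day 3 ZT4 replicates 1 and 2 and ZT16 replicates 3 and 4 had 253, 127, 45 and 122, and the other 18 libraries had 3 to 11.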

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

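The tests on immediate early genes, on the 4 day 3 libraries and on the clock after injury were chosen after the results were seen, and the counts over other splits of the libraries were chosen before the data were examined.

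In 2 of the 3 uninjured ZT16 libraries, replicates 1 and 3, the mean log2 CPM of 20 immediate early and stress genes was 10.58 and 10.55, against 6.54 in ZT16 replicate 2 and 5.59, 6.37 and 4.94 in the ZT4 libraries. RNA of other cell types raised in both libraries was argued against. The highest ratio of the lower of these 2 libraries to the highest of the other 4, over 9 marker lists, was 0.875. This ratio cannot show an excess in only 1 of them. Replicate 1 had a macrophage sum of 108.13 CPM, against at most 47.59 in the other uninjured libraries. Its endothelial sum was 247.62 CPM, against at most 195.43. A response to handling before fixation may account for the pattern, but ZT16 replicate 2 lay 0.16 above the highest ZT4 library and is a single library, so handling cannot be told apart from time of day.

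Genes that should be silent in muscle were detected in 4 day 3 libraries, a signal outside the comparisons. Olfactory receptor genes numbered 253 and 127 in ZT4 replicates 1 and 2 and 45 and 122 in ZT16 replicates 3 and 4, against 3 to 11 in the other 18 libraries. Deeper sequencing was argued against, since 0 of the 4 libraries were deeper than the median of the others. Genomic DNA in the library is consistent with the lowest of the 4 counts, 45. DNA itself was not measured here, and no biological explanation was tested.

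Clock genes differed between ZT16 and ZT4 in uninjured cells, and the median absolute log2 difference of 14 E-box genes was 1.23 there, 0.24 at day 1 and 0.34 at day 3. Too few counts after injury was argued against for the list as a whole, since the median standard error was at most 1.07 times that in uninjured cells. These errors rest on 1 spread per gene for all groups and on 4 libraries per injured group against 3. The median does not cover single genes at low levels, such as Hlf at 0.662 ± 0.363 and 0.803 ± 0.419 CPM at day 3. The hour of collection is not in the labels, so collection of both injured groups at the same hour may give the 0.24 at day 1, and it cannot be told apart from a clock damped by injury. The part of the 2 libraries with high immediate early genes stays open too: without both, the median log2 difference of the 14 genes was 1.21 and camera adjusted p = 1.79e-10 with the preset correlation, but ZT16 then rests on a single library, assumed to vary like the other groups.

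The effect of ZT16 over ZT4 differed from uninjured cells for 1125 genes at day 1 and for 1927 at day 3. In injured groups the labels attach the time to the injury, so these counts may set unlike times against each other. At day 1, differences past the test included Dbi 1.47, Trip10 −1.44, Iqsec3 1.88, Fdps 2.62, Arntl 2.19, Nfil3 −3.25, Per2 −2.12, Per3 −1.23, Cry1 −1.49, Nr1d2 −0.89, Dbp −1.01, Tef −1.05, Hlf −2.73, Bhlhe41 −1.38 and Usp2 −2.72 (log2). Nfil3 lost its call without uninjured ZT16 replicate 1, Usp2 without uninjured ZT4 replicate 2 or ZT16 replicate 3, and Per2 without any 1 of day 1 ZT4 replicates 2 and 4, day 1 ZT16 replicate 4, uninjured ZT4 replicate 2 and uninjured ZT16 replicates 1 and 3 (adjusted p from 0.0504 to 0.0836). Levels varied widely among the uninjured ZT16 libraries for Nfil3 (95.6 ± 62.5 CPM), Usp2 (648 ± 360) and Bhlhe40 (539 ± 343). Per3 lost its call without any 1 library of the 4 groups other than day 1 ZT4 replicate 3, day 1 ZT16 replicate 2 and uninjured ZT4 replicate 3, and Dbp without day 1 ZT4 replicate 1, 3 or 4, day 1 ZT16 replicate 1, 2 or 4, uninjured ZT4 replicate 1 or uninjured ZT16 replicate 1 or 2 (adjusted p from 0.0501 to 0.0922).

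At day 3, they were Dbi 1.74, Trip10 −1.78, Klf13 −2.31, Iqsec3 2.00, Wee1 −3.25, Arntl 2.19, Nfil3 −3.29, Per2 −2.76, Per3 −1.68, Cry1 −1.64, Cry2 −1.32, Nr1d2 −1.49, Tef −1.30, Hlf −2.52, Bhlhe40 −2.78, Bhlhe41 −1.55, Ciart −1.64 and Usp2 −3.11. Cry2 lost its call without day 3 ZT4 replicate 2 or 4, day 3 ZT16 replicate 3 or 4, uninjured ZT4 replicate 1 or 2 or uninjured ZT16 replicate 1 or 3, and Hlf without day 3 ZT4 replicate 1, 2 or 3, day 3 ZT16 replicate 1 or 2 or uninjured ZT16 replicate 1 or 3 (adjusted p from 0.0544 to 0.0948). Bhlhe40 lost its call without any 1 library of the 4 groups other than day 3 ZT16 replicate 1, uninjured ZT4 replicate 3 and uninjured ZT16 replicate 2, and Ciart without any 1 other than day 3 ZT4 replicate 4, day 3 ZT16 replicate 1 and uninjured ZT4 replicates 2 and 3 (adjusted p from 0.0528 to 0.118).

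A library lay far from the other 3 of its group in 23 of 381 groups of 4 libraries (6%), and chance flags about 1 in 20 groups. Day 1 ZT4 replicate 3 had a macrophage sum of 4710 CPM (others 2831 to 2985), with Itgam at 165 (at most 105 in the others), Il1b at 444 (141 to 192), Ccl2 at 515 (334 to 358) and Ppbp at 76.0 (40.4 to 44.5). It also had Myod1 at 1210 (1390 to 1400), Sparc at 745 (646 to 653) and Uqcrc1 at 617 (578 to 581). Day 1 ZT4 replicate 2 had Cenpe at 36.0 CPM (26.6 to 28.2). Day 1 ZT16 replicate 4 had an endothelial sum of 164 CPM (64.87 to 79.2), Nctc1 at 2.91 (12.6 to 14.2) and Ppbp at 29.1 (22.2 to 23.1). In day 3 ZT4, replicate 1 had Col4a1 at 44.1 (52.3 to 53.4) and Per2 at 7.38 (10.1 to 10.4), replicate 3 had Myh3 at 259 (338 to 349) and 11.62% of counts in its 50 highest genes (11.38 to 11.41%), and replicate 4 had Mfap5 at 52.4 (24.5 to 28.9). In day 3 ZT16, replicate 1 had Eno1 at 5120 (5520 to 5570) and Per3 at 2.77 (4.96 to 5.13), and replicate 2 had Nop58 at 324 (272 to 280). Replicate 4 of that group had Pax7 at 29.1 (20.8 to 22.1), Mfap5 at 21.3 (26.7 to 27.2) and Btg2 at 75.2 (124 to 133).

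Other splits of the same libraries were fitted in the same way. For uninjured ZT16 against ZT4, 10 splits are too few, with 2663 genes in the real split (1 of 10 as large) and 519 in the highest other. For day 1 against uninjured (11347 genes, highest other 1574), day 3 against uninjured (11606, highest other 8909) and day 3 against day 1 (8350, highest other 1), 1 of 40 splits was as large, the least possible. This argues against a chance assignment of libraries to states. Differences between mice or batches were not tested, as the labels do not say whether replicates are separate mice. Chance cannot be excluded for the time effect at day 1 against uninjured (1125 genes, 4 of 40 splits as large, highest other 2049). The 3 other splits that were as large kept the uninjured libraries of each time together, in place or with the times exchanged (1330 to 2049 genes). The other 36 called at most 55, so the structure of the uninjured libraries carries the count. For the time effect at day 3 against uninjured (1927 genes, 1 of 40 splits as large, highest other 847), the splits argue against chance only for the uninjured and day 3 libraries split together. The 2 other splits that kept the uninjured libraries of each time together called 826 to 847 genes and the other 37 at most 27, so that count draws on the same structure. The splits that kept it are too few to test the day 3 libraries alone. Where no gene passed, every split is as large by construction and the number of splits says nothing about chance. These were 35 of 35 for ZT16 against ZT4 at day 1 (highest other 1) and at day 3 (highest other 11), and 40 of 40 for the time effect at day 3 against day 1 (highest other 3). The split with 11 genes set the 4 day 3 libraries with olfactory receptor genes against the other 4.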

How the results depend on the processing

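The fits without uninjured ZT16 replicates 1 and 3, and without the 4 day 3 libraries with most genes detected, were chosen after seeing the data, and the other alternatives before the data were examined. Under alternatives, 23 counts of genes moved and 169 did not. A count moved if it changed over 1.5 times or, where the main count was 0, if any gene passed. For those that moved, the cause was not tested except where fewer libraries or another filter changed the genes or libraries fitted. For uninjured ZT16 against ZT4 (2663 genes) the count was 577 with only the groups compared, 467 without the 2 libraries and 1768 to 2898 without 1 library. For day 1 ZT16 against ZT4 (0) it was 270 without a filter on low counts, 27 in DESeq2, 46 in limma voom, 2 with only the groups compared, 1 with effective-length offsets and 0 to 10 without 1 library. For day 3 (0) it was 127 without the filter, 4 in DESeq2, 1 with only the groups compared and 0 without any 1 library. The time effect at day 1 against uninjured (1125) gave 737 in limma voom, 514 with only the groups compared, 134 without the 2 libraries and 648 to 1596 without 1 library, and that at day 3 against uninjured (1927) gave 473 without the 2 libraries, 661 without the 4 and 1309 to 2369 without 1. The time effect at day 3 against day 1 (0) gave 77 without the filter, 4 in DESeq2, 1 with effective-length offsets and 0 to 1 without 1 library. The counts for day 1 and day 3 against uninjured and day 3 against day 1 stayed within 1.5 times under each alternative, at 11139 to 11436, 11355 to 11676 and 7942 to 8255 without 1 library. Of gene values named, 4519 kept their direction and side of the threshold, 199 were no longer past it, 23 came past it and 3 changed sign, none of them called: Pax7 in uninjured cells to 0.03 with effective-length offsets and 0.06 without the 2 libraries, and Ccl2 at day 3 to 0.03 without the 4. Of list values, 1346 kept theirs, 160 lost the call and 6 changed sign, here as signed log10 of the adjusted p. Without the 2 libraries these were NF-kB (−0.07) in uninjured cells, the unfolded protein list (0.26) in the time effect at day 1, and NF-kB (0.01), extracellular matrix (0.01) and the unfolded protein list (0.19) in that at day 3, and without the 4 libraries interferon (−0.02) at day 3. Fitting replicate number as a block gave 2603 genes for uninjured ZT16 against ZT4, and correlations of libraries with the same number ran from −0.098 to 0.09, best with their own number in 3 of 11.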

Other observations

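The 3 gene lists here and the tests on them were chosen after seeing the data, and their p-values are not adjusted over lists. Genes of sterol synthesis and its regulation were lower at ZT16 in uninjured cells, with 17 of 22 fallen and none risen in edgeR (median log2 −1.33, camera p = 2.29e-25, and p = 0.00218 with an estimated correlation). Sqle, which encodes squalene epoxidase, went from 133 ± 43.2 to 22.9 ± 8.34 CPM (−2.54 ± 0.30) and Srebf2, the transcription factor that drives these genes, from 299 ± 18.1 to 126 ± 15.4 (−1.24 ± 0.12). The lanosterol synthase gene Lss fell by 1.93 ± 0.22. Without ZT16 replicates 1 and 3 the median was −1.50. At day 1 and day 3 no member passed between the times in edgeR. The time effect differed from uninjured cells for 17 of 22 genes at each day. Glucocorticoid response genes rose at ZT16 in uninjured cells in 10 of 11 (median 1.78, camera p = 1.26e-10, and p = 0.00584 with an estimated correlation), with Fkbp5, a steroid receptor cochaperone gene, at 2.27 ± 0.33, Tsc22d3 at 2.37 ± 0.50, Cebpd at 3.37 ± 0.65 and Zbtb16 at 1.78 ± 0.52. Without replicates 1 and 3 the median was 1.23.

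Mast cell genes at day 1 were lower at ZT16 than at ZT4 in all 10 members, none of which passed in edgeR (median log2 −1.69, camera p = 5.27e-14, and p = 0.00143 with an estimated correlation). The tryptase gene Tpsb2 was at 70.2 ± 15 CPM at ZT4 and 19.7 ± 10.1 at ZT16 (n = 4 and 4), the carboxypeptidase gene Cpa3 at 35.2 ± 8.48 and 11.8 ± 6.61 (−1.57 ± 0.47) and the histidine decarboxylase gene Hdc at 34.2 ± 10.4 and 9.87 ± 6.27 (−1.80 ± 0.50). All 10 rose at day 1 against uninjured.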
